A study of Mus musculus with 16 samples.

How the data were processed

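Genomic DNA from tails of 8 mice of 1 family was hybridised with DNA of 1 reference male on 16 two-colour Agilent arrays of a custom design, 2 arrays per mouse with the dyes exchanged. Per the file headers, the authors scanned the arrays and extracted them with Feature Extraction 10.7.1.1, and probe positions are on mouse build mm9. The deposited scanner files hold spot intensity values on a linear scale: the processed signals and the median spot and background signals. The processed signals were corrected with a fitted background surface and a multiplicative detrend surface and scaled by a linear dye factor per channel, per the file headers. The deposited LogRatio column is the log10 of the processed Cy5 signal over the processed Cy3 signal. The deposited series matrix holds log2 ratios. Set against each array's scanner values its columns had a slope of 1 or -1 according to dye, so they are log2 of reference over mouse. Their medians lay between -0.007 and 0.024, and how that small offset was set is not given in the sources used here. The columns were therefore turned in sign before use.

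In all steps the log2 ratio is mouse over reference, with the dye of each channel taken from the labels. The main values were log2 ratios of the processed signals, centred on the median of autosomal probes of each array, with no loess or quantile step, since many probes of this array were chosen for a copy number difference. Control spots were left out, and so were spots with outlier flags, between 0.085% and 0.185% of probe spots per array. There were 0 saturated spots. Replicate spots of a probe were averaged, and 1025 probes had more than 1 spot. Both arrays of a mouse were averaged into 1 replicate, so n counts mice. Between arrays of 1 dye orientation the correlation over probes was between 0.29 and 0.77 for all pairs of mice. Between the orientations of a mouse, after turning the sign, it was between -0.40 and 0.26, so calls were required in both orientations. The spread of adjacent probes in the averaged profile was between 0.050 and 0.094 on the log2 scale.

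Intervals were called in each mouse by a recursive interval score, the sum of log2 ratios over the spread divided by the square root of the number of probes. The score had to reach 6, over at least 3 probes, with an absolute mean log2 ratio of at least 0.25 in the average and in each dye orientation with the same sign, and no gap over 100 kb. Overlapping intervals of different mice were joined into regions. An offspring-only region was called in at least 1 offspring and in neither parent, and exceeded each parent by at least 0.25 in the average and in both orientations. Noise was measured by calling with the same score, probe, size and gap limits on the unturned mean of both arrays of a mouse minus its mean over mice, in which copy number cancels. The rule on separate orientations cannot apply to that signal, and the mean over mice was removed from it alone. On profiles with no aligned signal in which 200 intervals per mouse were planted, 91.7% of gains of 0.4 and 93.3% of losses of 0.4 over 3 probes were found, and 1 interval was called where none was planted over all 8 mice. That 1 is not the number of false calls in the real profiles, for which other estimates were higher. The dye-cancelling signal gave 32 intervals, and simulated families of unchanged mice sharing 1 reference gave a median of 53 regions.

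Probes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the mean log2 ratio per mouse, with 6 offspring against 2 parents and with 8 mice against 0, and Benjamini-Hochberg adjustment. The fits were tested on simulated data with 200 probes changed alike in all 6 offspring, or in all 8 mice for the comparison with 0. Counts per mouse and region means were compared with two-sided exact permutation tests. Calling used Python 3.11.15 with numpy 2.4.6, numba 0.67.0 and scipy 1.17.1. The slides held 4 arrays each: slide 1 the parents, slide 2 offspring 1 and 2, slide 3 offspring 3 and 4, and slide 4 offspring 5 and 6. Slides 1 and 2 were in scan 1 and slides 3 and 4 in scan 2.

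Regions to be named were fixed before the data were examined: the 10 offspring-only regions with the largest difference from the nearer parent, the 10 largest regions called in all 8 mice, the 5 largest called in 1 parent only, the 5 largest called in exactly 1 mouse, and the 5 probes in each direction with the smallest adjusted p of each limma comparison. Regions called in 4 or more mice were named after their values were seen. The files give probe positions without gene names, and the gene table at hand is on a later build, so no genes are named. The gene lists fixed beforehand, families of receptors, defensins, urinary proteins and other tandem genes, were not analysed here for that reason. X and Y probes were used only to describe the mice, and all calling was on the 19 autosomes. Alternatives covered background correction (normexp with offset 50, on median spot signals since mean signals were not used here), centring, source of the ratio, filters, thresholds, dye orientation, joining rule, blocks and left-out mice. Data are tail DNA, and the share of cells that carry a change was not measured.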

Results

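Copy number was measured in tail DNA of a single mouse family of strain C57BL/6 by comparative genomic hybridisation, in which the DNA of a mouse and of a reference animal are labelled with different dyes and compete for the same probes. The family held 1 sire, 1 dam and 6 offspring, here offspring 1 to 6. Each of the 8 mice was compared with the same reference male on 2 arrays with the dyes exchanged, so 16 arrays gave 1 averaged profile per mouse. The series concerns offspring of males kept under gamma rays at 0.05 mGy per day for 400 days, and asks whether copy number changes appear in offspring and not in their parents. Its title places this family in the exposed series, whereas its design text describes this sire as not irradiated. The sire's exposure is therefore unresolved, and no comparison below is a comparison of doses. The array carried 112379 autosomal probes, 48 X probes and 3 Y probes. Per the design text its probes were packed around positions picked in a first screen of these mice, so counts below describe selected sequence and not the whole genome. Median processed intensity per array lay between 945 and 973 in Cy3 and between 931 and 966 in Cy5, and between 98.1% and 99.6% of probe spots were well above background. The number of arrays limits the precision. Each mouse has 1 DNA sample, and the values from the 2 dye orientations show technical spread only.

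The X and Y probes parted the 8 mice. The median log2 ratio of mouse over reference on X was 0.01 in the sire and 0.86 in the dam. It was 0.01 in offspring 1 and between 0.81 and 0.89 in offspring 2 to 6. On the 3 Y probes the median was -0.03 in the sire, -1.67 in the dam and 0.00 in offspring 1. Offspring 2 to 6 lay between -1.78 and -1.37 on Y. The labels do not give the sex of the offspring. On X and Y offspring 1 lay at the sire's level and offspring 2 to 6 near the dam's. This is the pattern of a male and of females against a male reference.

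The first question was which regions differed from the reference male in any mouse. A gain of 161.997 kb on chromosome 4, from 101109089 to 101271085 (mm9), was called in both parents and in 5 of 6 offspring. It spanned 1360 probes. Its mean log2 ratio was 0.39 in the sire, with 0.42 and 0.36 in the separate dye orientations, and 0.40 in the dam, with 0.41 and 0.38. Offspring 1, 3 and 4 were at 0.35, 0.39 and 0.39. Offspring 2 and offspring 6 were both at 0.62, and offspring 5 was at -0.01 and was not called. Expressed as a ratio, the parents were at 1.31 and 1.32 times the reference and offspring 2 and 6 at 1.54 times. The 54 flanking probes on the same stretch averaged between 0.00 and 0.04 in all 8 mice. Intervals called in the carriers started at the same probe in every one of the 7 mice and ended between 101270967 and 101271085. The nearest unaffected probes started at 101108990 and 101271130, just outside both edges.

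**Figure D1:**
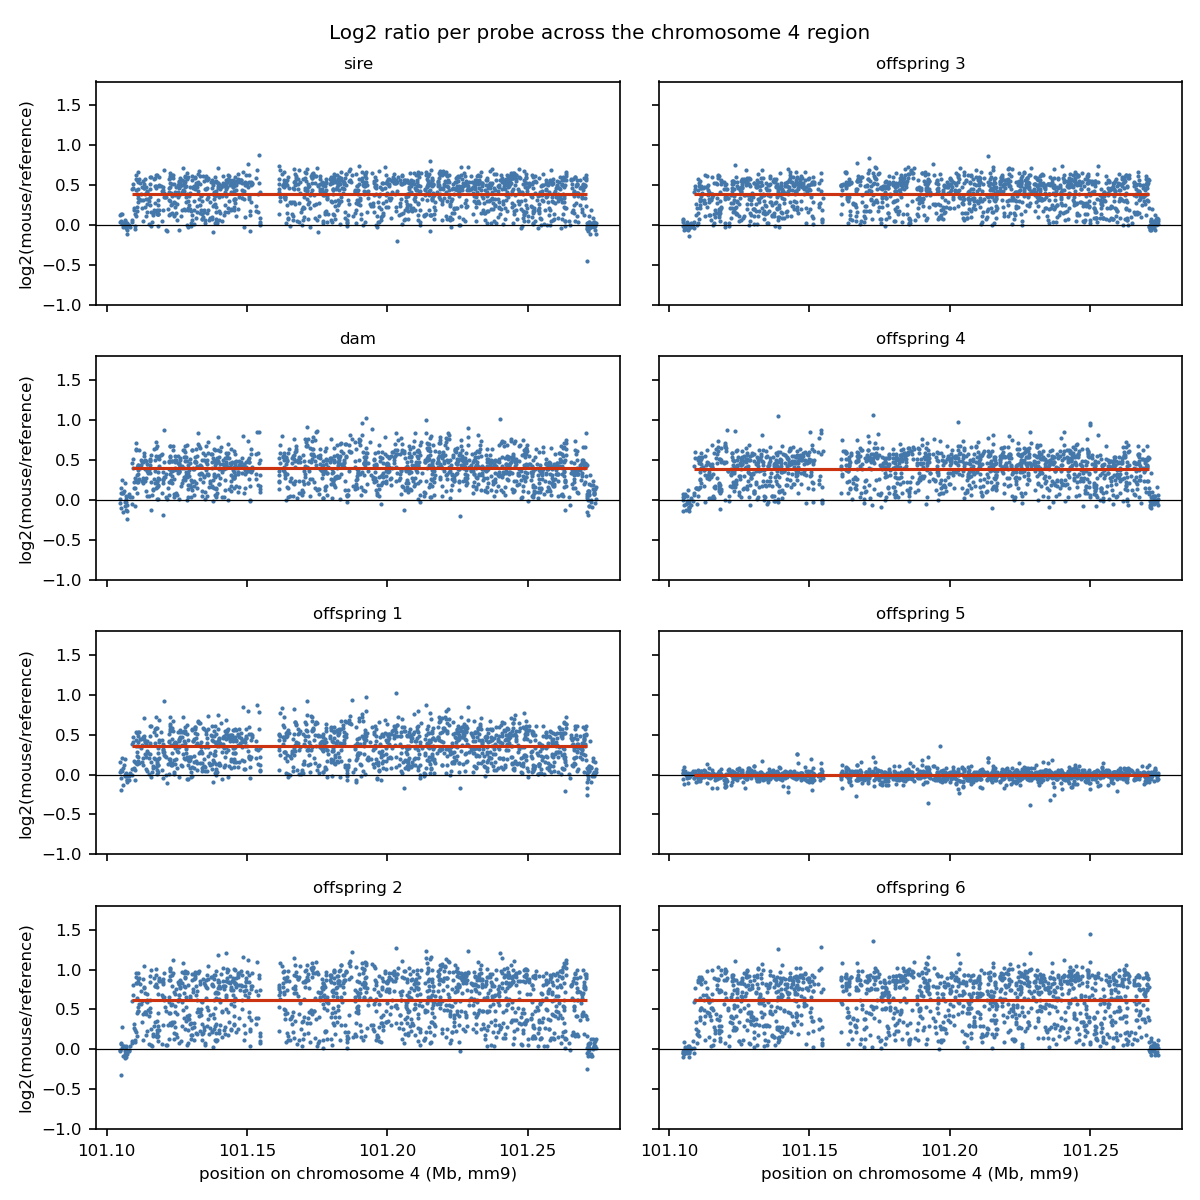
Log2 ratio of mouse over reference (vertical axis) of each probe by position on chromosome 4 in Mb (horizontal axis), 1 panel per mouse. Points are probes averaged over both dye orientations and the red line is the mean over the region, which is -0.01 in offspring 5, 0.62 in offspring 2 and 6, and between 0.35 and 0.40 in the other mice.

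Low ratios at 3 further positions were shared by the dam and most offspring. On chromosome 3, 148 probes from 25416456 to 25456288 (39.833 kb) had a mean log2 ratio of -1.80 in the dam. Offspring 2 to 6 lay between -1.80 and -1.68 there, while the sire was at 0.00 and offspring 1 at 0.02. On chromosome 5, 4 probes from 80244548 to 80244925 gave -2.94 in the dam and between -3.06 and -2.85 in offspring 2 to 6. The sire and offspring 1 were at 0.02 and 0.03 on these probes. On chromosome 7, 5 probes from 36353657 to 36356045 gave -0.56 in the dam, and the region was also called in offspring 2, 5 and 6. Offspring 3 and 4 were at -0.50 each on chromosome 7 but missed the required size in the Cy5 orientation, at -0.20 each. The sire and offspring 1 were at -0.01 and -0.02. The dye orientations differed by at most 0.06 on chromosome 3, 0.48 on chromosome 5 and 0.64 on chromosome 7.

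**Figure D2:**
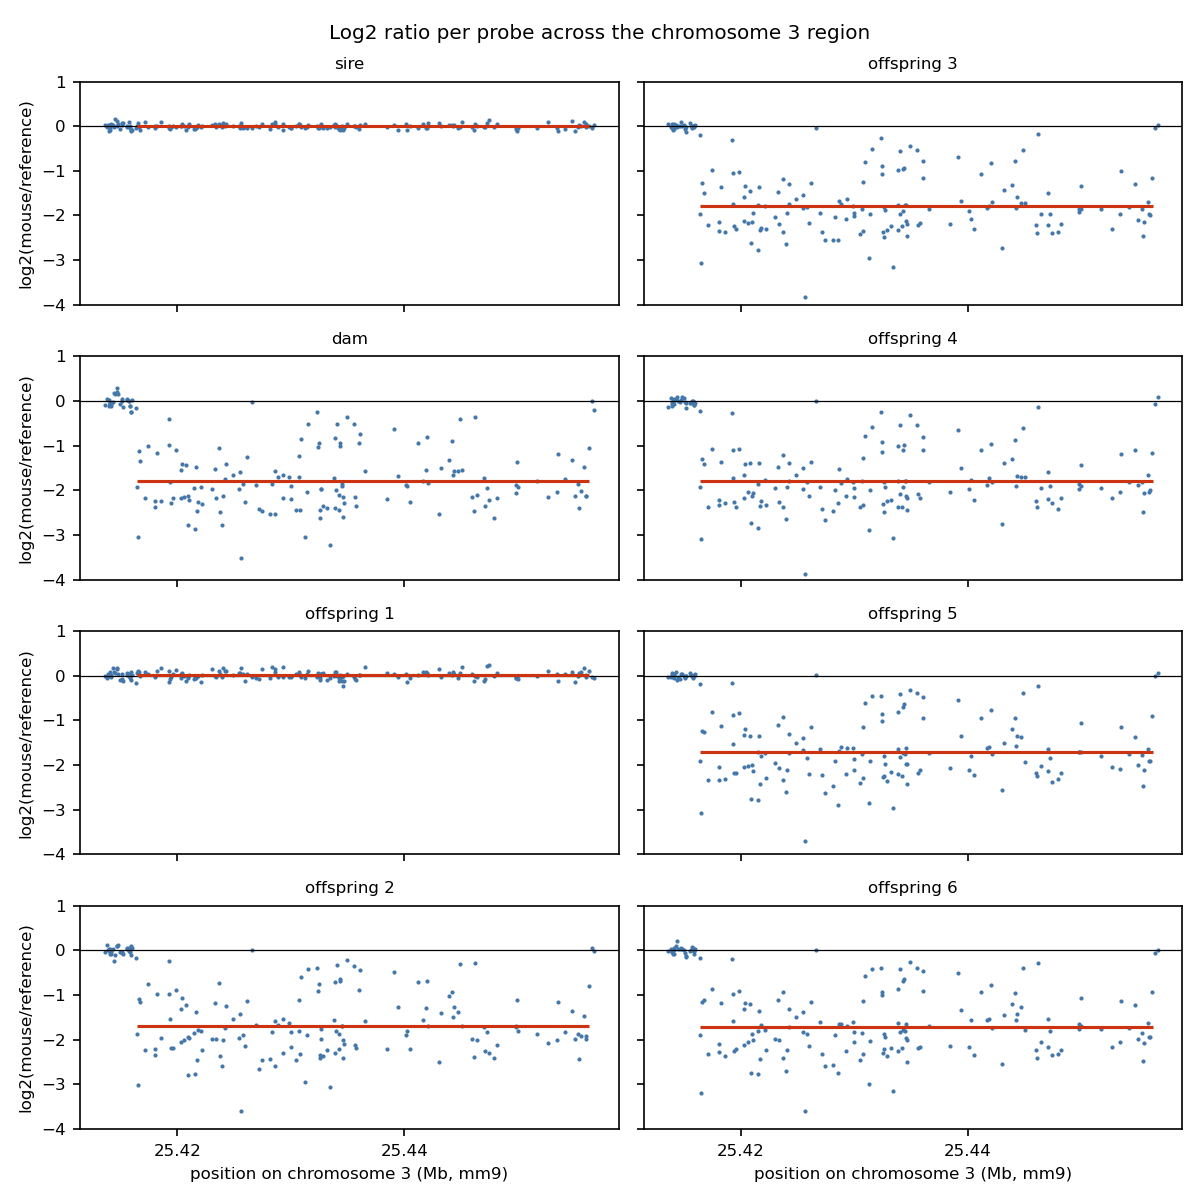
Log2 ratio of mouse over reference (vertical axis) of each probe by position on chromosome 3 in Mb (horizontal axis), 1 panel per mouse. Points are probes averaged over both dye orientations and the red line is the mean over the region, which lies between -1.80 and -1.68 in the dam and offspring 2 to 6 and between 0.00 and 0.02 in the sire and offspring 1.

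**Figure D3:**
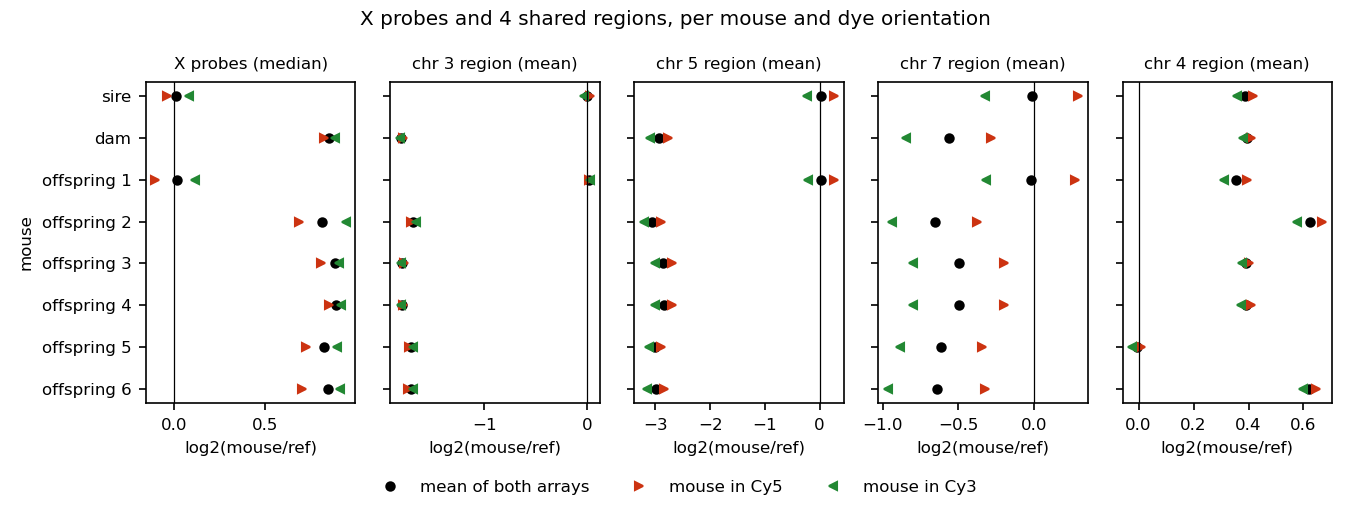
Log2 ratio of mouse over reference (horizontal axes) for each mouse (vertical axis): the median over X probes and the mean over the shared regions of chromosomes 3, 5, 7 and 4. Circles are the average of both arrays and triangles the separate dye orientations. The circles of the dam and offspring 2 to 6 lie between -0.65 and -0.50 on chromosome 7 and between 0.81 and 0.89 on X. Those of the sire and offspring 1 lie between -0.02 and 0.03 on X and on chromosomes 3, 5 and 7. Their triangles lie farther out: on chromosome 7 at 0.29 (Cy5) and -0.32 (Cy3) in the sire and at 0.27 and -0.31 in offspring 1.

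A weaker shared loss lay on chromosome 9, from 33535388 to 33535741, over 6 probes. It was called in the sire, the dam, offspring 1 and offspring 4, and its mean log2 ratio was between -0.50 and -0.27 in all 8 mice. On chromosome 4 the offspring averaged 0.40 ± 0.23 (SD, n = 6) and the parents 0.39 (n = 2), with p = 1 in a two-sided exact permutation test over 28 splits. On chromosome 9 the exact permutation p was 0.857. On chromosomes 3, 5 and 7 the 2 parents lie at different levels, so the parents' mean is the value of no mouse and the test says nothing on a change from parent to offspring. There the p values were 0.929, 0.5 and 0.429, and all 5 were 1 after Benjamini-Hochberg adjustment. The two-sided p is 2 times the smaller one-sided share of the 28 splits. Its smallest possible value is therefore above 0.0357, the share of 1 split, and above 0.05.

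In all, 159 regions were called in at least 1 mouse, 58 of them gains, 99 losses and 2 with both directions. Only the chromosome 4 and chromosome 3 regions held 20 or more probes, and the median region held 4 probes and spanned 329 bases. Intervals numbered 78 in offspring 1, 48 in offspring 4 and 34 in the dam, and between 4 and 8 in each other mouse. Calling without the rule on separate orientations, on the part of the signal in which copy number cancels between dye orientations, gave 32 intervals over the 8 mice, against 191 called. With at least 5 probes 60 regions were left, and without offspring 1 and offspring 4, a choice made after seeing the data, 48 were left. In 20 simulated families of unchanged mice sharing 1 reference, a median of 53 regions was called in any mouse. In them at most 5 regions were called in 2 or more mice and at most 1 in 4 or more, against 13 and 6 observed.

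**Figure D4:**
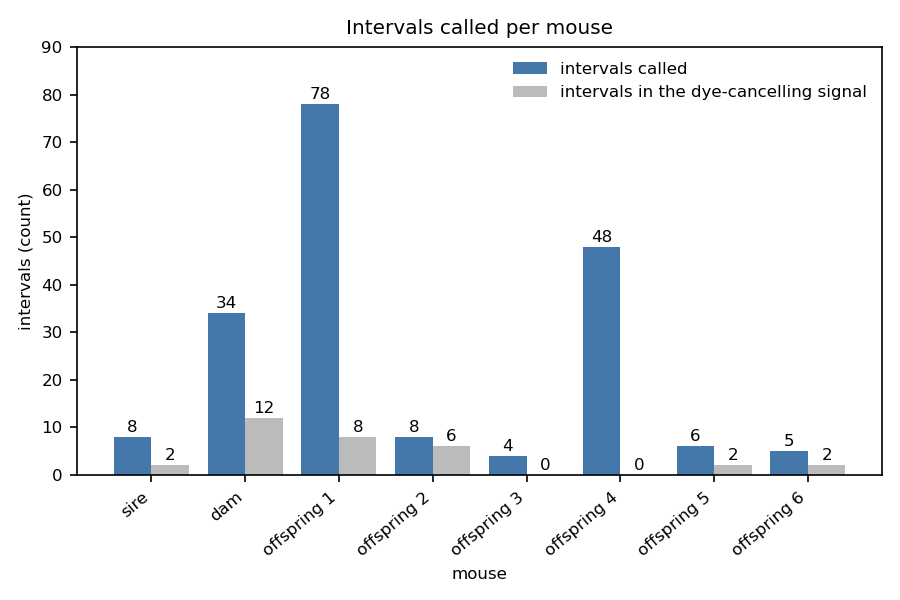
Number of intervals called (vertical axis) in each mouse (horizontal axis). Blue bars are intervals called in the averaged profile and grey bars those called in the dye-cancelling signal; offspring 1 has 78 against 8, offspring 4 has 48 against 0, and the dam 34 against 12.

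A state carried by the reference male alone would appear in every mouse, so regions called in all 8 mice were counted. There were 0 such regions, a count that depended on the settings: it was 1 with no requirement on single orientations, 1 at a size of 0.15, 1 on arrays with the mouse in Cy5 alone and 2 on those with the mouse in Cy3 alone. The average over the chromosome 9 region was below -0.25 in all 8 mice, though it was called in 4. By calls the chromosome 4 gain came closest, with 7 mice, and leaving out offspring 5 made it the 1 region called in every remaining mouse.

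The question of changes new in the offspring was addressed by regions called in an offspring and in neither parent. There were 44 offspring-only regions, of which 22 lay in offspring 1, 21 in offspring 4 and 1 in offspring 5. There were 0 in offspring 2, 3 and 6. Gains numbered 21 and losses 23, and each spanned between 3 and 9 probes. The difference between the offspring and the nearer parent had a median size of 0.38 and a maximum of 0.58. The largest was a gain of 4 probes in offspring 4 on chromosome 6, from 24606371 to 24606591, at 0.46 in offspring 4 and -0.13 and -0.12 in sire and dam. Next came gains in offspring 4 on chromosome 15, from 26510303 to 26510585 at 0.38, and on chromosome 10, from 124465583 to 124465771 at 0.44. The other gains of offspring 4 among the 10 largest lay on chromosome 1 (194827536 to 194827675, at 0.46), on chromosome 3 (83612797 to 83612963, at 0.43) and on chromosome 5. The 3 on chromosome 5 started at 7072096, 64186590 and 50970715 and were at 0.45, 0.42 and 0.43. Offspring 1 supplied 2 losses among the 10. On chromosome 18, from 63414509 to 63414648, offspring 1 was at -0.66, the sire at -0.13 and the dam at 0.24. On chromosome 2, from 64884987 to 64885459, offspring 1 was at -0.78, the sire at -0.26 and the dam at -0.07. After normexp background correction the difference from the nearer parent shrank from -0.54 to -0.17 on chromosome 18 and from -0.53 to -0.31 on chromosome 2. Neither loss was then called as offspring-only, nor was the chromosome 15 gain of offspring 4, whose difference went from 0.58 to 0.47. None of the 44 regions was carried by all offspring, and the count is not stable to settings. It was 9 with at least 5 probes, 0 with at least 20 probes, a setting added after seeing the data, and 26 after normexp background correction, and leaving out offspring 1 or offspring 4 gave 22 or 23, leaving out both 1.

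Regions called in exactly 1 mouse gave the same definition for parents and offspring. There were 146, with 72 in offspring 1, 39 in offspring 4, 25 in the dam, 4 in the sire, 3 each in offspring 2 and offspring 5 and 0 in offspring 3 and offspring 6. A mouse without a call was not always at another level. On chromosome 3, from 74775608 to 74776186, only offspring 5 was called, at 0.33. There the dam was at 0.37 and offspring 2, 3, 4 and 6 at 0.38, 0.28, 0.30 and 0.25. The sire was at 0.03 and offspring 1 at -0.09, so these averages part the mice as the X probes do. In offspring 1, 71 of the 72 were losses, with a median size of 0.44. Over these 71 losses the sire had a median log2 ratio of -0.19 and offspring 5 of 0.13. In offspring 4, 34 of the 39 were gains, over which offspring 6 had a median of 0.15 and the sire of -0.05. In the dam 17 of 25 were gains. The 5 largest were losses of offspring 1 on chromosome 2 (64884987 to 64885459, at -0.78), chromosome 13 (113005727 to 113005862, at -0.73), chromosome 16 (9525205 to 9525355, at -0.70), chromosome 3 (63035176 to 63035313, at -0.67) and chromosome 18 (63414509 to 63414648, at -0.66). The sire was also below 0 in all 5, between -0.34 and -0.13. Offspring carried 19.5 ± 29.8 such regions (SD, n = 6) and parents 14.5 ± 14.8 (SD, n = 2), with p = 1 in a two-sided exact permutation test over 28 splits. Within scan 1, which held both parents and offspring 1 and 2, the means were 37.5 and 14.5, with an exact permutation p of 1 where the smallest possible is 0.333. Scan 2 held offspring only. Without offspring 1 the count of regions in exactly 1 mouse was 77.

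Transmission was followed in the 38 regions called in 1 parent only, 32 in the dam and 6 in the sire. In the direction of the parent, 30 of these were called in 0 offspring, 4 in 1 offspring and 4 in 2 or more, and 2 further calls in offspring went the opposite way. The dam had the largest spread of adjacent probes, 0.094, and 12 intervals in the dye-cancelling signal against 34 called. A region called in 0 offspring may therefore be noise in the parent, and these counts do not measure transmission. The 5 with the largest values were all in the dam. The chromosome 3 and chromosome 5 regions were each called in offspring 2 to 6, the 5 of 6 offspring whose X and Y probes also lay with the dam's, so no share of transmission is given. The chromosome 7 region was called in 3 of 6, but offspring 3 and 4, which missed the call in a single orientation, also had averages near the dam's, so it parts the offspring in the same way. On chromosome 14, from 29649150 to 29649340, the dam was at -0.55, and losses were also called in offspring 1 at -0.40 and offspring 3 at -0.31. Offspring 4 was called there as a gain, at 0.46. On chromosome 9, from 31171046 to 31171226, the dam was at -0.45 and offspring 4, the only offspring called, at 0.31. The count of 38 fell to 13 after normexp background correction, to 11 with at least 5 probes and to 14 with a score of 8.

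At single probes, offspring and parents were compared with limma over the 112379 probes. With Benjamini-Hochberg adjustment at 0.05, 0 probes differed, and the smallest adjusted p was 0.913. At an unadjusted p under 0.05 there were 5264 probes, where 5619 are expected by chance. That count moved with the mice: leaving out 1 mouse at a time gave 17756 without the sire, 8002 without offspring 1, and between 4021 and 5139 for each other mouse left out. On arrays with the mouse in Cy5 it was 7648. The smallest adjusted p in any of these was 0.0776, without the sire. Each slide held 1 group only, and with slide as a random block the count was again 0, as it was with scan as a block and within scan 1. The same fit was run on simulated data with probes changed alike in every offspring. It recovered 16.5% of probes changed by 0.25, 82.0% of those changed by 0.5 and 98.5% of those changed by 1. Recovery of a change in a single offspring was not tested, so the count of 0 decides nothing on such changes.

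Against the reference male, limma called 1469 probes over the 8 mice at an adjusted p under 0.05 and an absolute mean log2 ratio of at least 0.25, with 1124 higher and 345 lower. Of the higher probes, 1020 lay in the chromosome 4 region, and of the lower probes 144 lay in the chromosome 3 region. The mean of those 144 over the 8 mice, -1.34, is the level of no mouse. Over that region the sire was at 0.00 and offspring 1 at 0.02, and the other mice lay between -1.80 and -1.68. A further 270 lay outside every called region. The lower probe with the smallest adjusted p, A_67_P06862987 on chromosome 9 from 82868024 to 82868083, had a mean log2 ratio of -0.53 ± 0.03 (SE) and a limma adjusted p of 0.000155, and was below 0 in 8 of 8 mice. The next were A_67_P04475603 on chromosome 2 at -0.50, A_67_P01902122 on chromosome 9 at -0.47, A_67_P13923344 on chromosome 6 at -0.36 and A_67_P05162987 on chromosome 4 at -0.28. Probe A_67_P01902122 belongs to the chromosome 9 region called in 4 mice. The higher probe with the smallest adjusted p, A_67_P07959016 on chromosome 13 from 95707465 to 95707524, had a mean of 1.06 ± 0.08 (SE) and a limma adjusted p of 0.00109, and was above 0 in 8 of 8 mice, between 0.80 and 1.51. A_67_P08932383 on chromosome 18 was at 0.39, A_67_P00943892 in the chromosome 4 region at 0.71, A_67_P03222809 on chromosome 16 at 0.45 and A_67_P01572539 on chromosome 7 at 0.30. These values leave out the reference male's own spread, since it is 1 animal, and they treat 8 members of 1 family as independent mice. Single dye orientations called 7223 probes with the mouse in Cy5 and 6794 with the mouse in Cy3.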

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

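The tests on chromosomes 3, 5 and 7 below were chosen after the result was seen, except that of the reference channel's brightness, and that of independent inheritance replaced a count over these 3 regions alone. Of 25 sets of 6 offspring values examined, 7 had 1 mouse far from the others, each time offspring 1. Chance marks about 1 in 20 sets that were not chosen for their values, which is no yardstick here. The sets on chromosomes 3, 5, 7, X and Y show the same split of the mice, and those on chromosomes 18 and 16 were named because they were called in offspring 1 alone. Offspring 1 was at 0.0155 on the chromosome 3 region, at 0.0303 on the chromosome 5 region and at -0.0224 on the chromosome 7 region, where the other offspring were between -1.80 and -1.68, between -3.06 and -2.85 and between -0.65 and -0.50. Its X probes had a median of 0.0132 against 0.81 to 0.89 in the others, and its Y probes -0.00152 against -1.78 to -1.37. In small regions called in it alone it was at -0.66 on chromosome 18, with the others between -0.16 and 0.10, and at -0.70 on chromosome 16, with the others between -0.14 and 0.20.

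The low values of the dam and offspring 2 to 6 on chromosomes 3, 5 and 7 follow the X and Y probes. An effect of dye or of single arrays is argued against on chromosome 3, where the orientation value nearest to 0 in these 6 mice was -1.66. Independent inheritance of 3 autosomal losses was tested on the 4 regions called in 1 parent only and in at least 2 offspring in its direction. The regions of chromosomes 3, 5 and 7 put offspring 1 nearer to the sire and offspring 2 to 6 nearer to the dam. The chromosome 14 region parts the same mice with the sides exchanged. An exact enumeration gave p = 0.00121 for 3 of 4 agreeing, over splits with at least 2 offspring on the dam's side. The chromosome 14 split has only offspring 1 on that side, so it is not among these splits. The 3 agreeing regions also prompted the test, so its p decides nothing. Extra copies of these sequences on the Y chromosome stay open: 18 of 18 pairs of offspring and region go with the X probes, but this is 1 split of 6 offspring seen 3 times, and it prompted the explanation, so it is no support. Whether sequence is extra in the reference male or missing in the low mice was not decided by brightness. The reference channel over the chromosome 3 probes was brighter than 99.7% of other windows of 148 probes, which met its bound for extra copies. The channels of the sire and offspring 1 were also brighter than 99.7% of windows. Those of the dam and offspring 2 to 6 were brighter than between 39.9% and 52.2% of windows. Levels of different probes are not comparable, so the test is void and decides nothing. A plain loss passed on by the dam is argued against on chromosomes 3 and 5. Offspring 2 to 6 lay there at 0.288 to 0.311 and 0.120 to 0.139 times the reference. That is below the level a single copy from the sire would leave, unless the sire's 2 chromosomes differ there. Other forms of loss stay open, as do extra copies. The Y position itself was not tested.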

How the results depend on the processing

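The alternatives with at least 20 probes, without offspring 1 and offspring 4, with the brightness and length trend removed, with scan as a block and within scan 1 were chosen after seeing the data. Counts of regions depended on thresholds and on dye orientation, and the cause was not tested except where fewer probes or mice entered by construction. Against 159 regions in any mouse, 44 offspring-only, 146 in exactly 1 mouse and 38 in 1 parent only, normexp background gave 98, 26, 88 and 13. At least 5 probes gave 60, 9, 54 and 11, at least 20 probes gave 2, 0, 0 and 1, and a size of 0.4 gave 49, 22, 45 and 5. A size of 0.15 gave 359 in any mouse, 289 in exactly 1 and 133 in 1 parent only, with 1 region in all 8 mice. With no requirement on single orientations the counts were 276, 75, 226 and 96, with 1 region in all 8 mice. Only arrays with the mouse in Cy5 gave 474, 92, 355 and 216, with 1 in all 8, and only arrays with the mouse in Cy3 gave 362, 87, 248 and 89, with 2 in all 8. A score of 8 gave 14 regions in 1 parent only. Without offspring 1 and offspring 4 there were 48 in any mouse, 1 offspring-only and 42 in exactly 1 mouse. Leaving out 1 mouse at a time gave between 77 (without offspring 1) and 147 regions in exactly 1 mouse, between 22 and 44 offspring-only regions (22 without offspring 1, 23 without offspring 4), and 0 or 1 in all 8 mice. Probes of the 8 mice against the reference numbered 7223 on Cy5 arrays, with 3356 higher and 3867 lower, and 6794 on Cy3 arrays, against 1469; leaving out 1 mouse gave between 1391 and 1543. All other settings run for these counts, such as centring, the deposited LogRatio, series matrix values, flags, gap and joining rule, stayed within 1.5 times. Offspring against parents gave 0 probes in every setting, leave-one-out fits included, where a lone parent is assumed to vary like the offspring; the smallest adjusted p was 0.0776, without the sire. A count within 1.5 times need not hold the same regions. Segmenting offspring minus parent directly gave 46 offspring-only regions, which held 25 of the 44. With the brightness and length trend removed there were 41, which held 30 of the 44. The mean of the chromosome 4 gain over its carriers stayed between 0.41 and 0.48, that of the chromosome 3 region between -1.76 and -1.63 and that of the chromosome 5 region between -3.10 and -2.80. The chromosome 7 region depended on dye, from -0.33 on Cy5 arrays to -0.91 on Cy3 arrays, against -0.62, and the chromosome 9 region ranged from -0.45 to -0.36. Of the 10 named offspring-only regions, 10 were no longer called as such with at least 5 probes, 7 on Cy3 arrays alone, 6 at a size of 0.4, 3 on Cy5 arrays alone and 3 after normexp background correction. Removal of a GC trend was not run, since probe sequences were not used here, nor were the gene list alternatives. No paired analysis was possible because the sire and dam are single mice. At least 98.1% of probe spots per channel were well above background, and requiring this on all arrays kept every count within 1.5 times.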

Other observations

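The tests of the chromosome 4 gain and of the small one-mouse regions were chosen after the results were seen, and that of the trend was changed after a first result, in which the share of regions still called left offspring 4 open at 59.0%. The chromosome 4 gain lay at 3 levels. Taking the parents' excess over the reference, a ratio of 1.31, as 1 step, offspring 5 was at -0.02 steps, offspring 1, 3 and 4 at 0.89, 1.00 and 1.00, and offspring 2 and 6 at 1.73 each. A slide or scan effect is argued against, since mice of the same slide differed by up to 0.63, between offspring 5 and offspring 6. A candidate explanation is 1 extra copy in each parent, passed on independently: the counts of 1, 3 and 2 offspring nearest to 0, 1 and 2 steps gave an exact multinomial p of 1 against 1:2:1. With 6 offspring many other ratios would pass too, and 1.73 lies below 2. The step was taken from the parents' own ratio and each offspring was put at the nearest of 0, 1 and 2 steps. The test therefore says nothing on the number of copies, and whether a ratio of 1.31 is that of 1 extra copy was not tested. As the gain was called in both parents, it is not new in the offspring, and offspring 5 lay at the level of the reference male.

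The small regions called in offspring 1 only and in offspring 4 only are not explained by random noise of the single arrays, since the dye-cancelling signal gave 6.35% as many intervals in these mice. Over the 71 losses of offspring 1 the sire had a median of -0.19 and was below 0 in 71 of 71, while offspring 5 had 0.13, and sire minus offspring 5, in which the reference cancels, had a median of -0.30. Over the 34 gains of offspring 4, offspring 6 minus sire had a median of 0.19, with offspring 6 at 0.15 and the other mice between -0.05 and 0.02. Both differences passed the bounds set for a graded signal shared with other mice, but their mice were picked from these medians, so the tests are void and that explanation stays open in both. An average trend with probe brightness and probe length is argued against as the whole source by size: after its removal the regions kept a median of 104% of it in offspring 1 and 91.9% in offspring 4 (quartiles 89.5% and 94.2%). The 71 losses of offspring 1 and 34 gains of offspring 4 did lie on dimmer probes. Their median brightness was 8.81 and 8.72, against 9.92 over all probes. The 5 losses of offspring 4 lay on brighter ones, at 10.5. An effect limited to part of the dim probes was not tested. Background correction mattered for such counts: with normexp, regions called in exactly 1 mouse numbered 88 over all mice, against 146. The calls of offspring 4 were not all kept: its median size went from 0.38 (quartiles 0.31 and 0.43) to 0.35 (0.29 and 0.41), and of 39 calls 16 ended, 4 with the average and 8 with 1 or both orientations below 0.25, and 4 for other reasons. No biological explanation was tested.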
